A study of Mus musculus with 10 samples.

How the data were processed

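RNA of 10 wells of primary mouse tracheal epithelial cells at an air-liquid interface, 4 inoculated with Sendai virus strain 52 and 6 with the same amount of virus inactivated by ultraviolet light, was measured on 1 Affymetrix MG_U74Av2 array per well. Per the labels' protocols, total RNA was converted to poly(A)+ RNA, amplified and labelled with biotin. The authors deposited 1 value per probe set and array. The submitters' processing notes name GCRMA, which corrects background from probe sequence, normalizes between arrays and summarises the probes of a set, and limma, with no versions, and the series description states quality control with simpleaffy in Bioconductor 2.0. The deposited values were taken as log2: their base is not stated, and values between -0.93 and 14.87 fit a log2 scale. They are values of single arrays and not ratios, so they have no direction to settle, and array medians between 3.59 and 4.04 show that they were not centred on 0. The log base is thus the part that stays unknown. The role of limma in the deposited values and a genome build are not given in the sources used here, so no genomic positions are printed.

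Of 12488 probe sets, 66 were control probe sets, 10833 had 1 gene symbol in the platform annotation, 396 several and 1193 none listed, and only those with 1 symbol were named. Symbols were updated by Entrez identifier through the RefSeq gene table of assembly GRCm38.p6, used for names alone, in which 10817 of these probe sets had a match. Probe sets above 4 (log2) on at least 4 arrays were kept, which left 4808, and the probe set with the highest mean over the 10 arrays stood for its gene, which left 4201 genes, 548 of them with more than 1 kept probe set. For Relb another kept probe set gave a log2 fold change of 0.16 against 1.15 on the one used. Slpi had 3 further kept probe sets at 0.18, 0.58 and 1.11 against 1.66, and Atf3 had 1 at 3.47 against 4.62. Why probe sets of the same gene differed was not tested.

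Groups were taken from the sample titles. SeV was compared with UV-SeV in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, with no covariate, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, and genes changed at least 2-fold were counted in addition. Detection calls were not used here, so for named genes with a group mean below 4 (log2), on all arrays or with 1 left out, the fold is printed as a lower bound with values below 4 raised to 4, beside the log2 fold change as deposited. Standard errors of fold changes are those of this fit, and each group's error is the SD over its arrays. The labels name no batch. The title numbers fall into 2 runs with 2 SeV and 3 UV-SeV arrays each, and the run served as a block, as separate fits and in an interaction with treatment. The signal of the arrays gives no depth, and precision rests on the number of arrays.

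Gene lists for airway epithelium and paramyxovirus infection, 32 lists with 805 names, were fixed with the model, the filter, the naming rule and most alternatives before the data were examined. The 31 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, adjusted over the lists. Alternatives were camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way. Named genes were the 8 largest increases and the 8 largest decreases past the threshold with groups that did not overlap, the 2 members of each list with the smallest p, with those of lists that did not pass left out unless stated, and Ifnb1, Irf7, Cxcl10, Ccl5, Foxj1, Scgb1a1, Krt5, Muc5ac, Actb and Gapdh whatever their values. A further gene fixed by name is not reported here.

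Alternatives were no filter and a stricter one at 6, quantile normalization, a shift of each array to a common median, the mean of a gene's probe sets, each probe set on its own, a floor of 4, eBayes with trend and robust options, array weights, the run as a block, each run alone, an adjusted p of 0.01, treat with a fold bound of 1.5 and each array left out in turn. Leaving out UV-SeV 3663 and SeV 3483 together, and the alternatives for the agreement of the runs, were chosen after seeing the data. The fit was tested on simulated data for SeV against UV-SeV over 4201 genes. Of 100 genes with a log2 change of 1, 55 were called in the right direction, of 100 with a change of 2, 88, and of 4001 unchanged genes, 8. Of 31 simulated lists, 5 of 5 shifted ones and 0 of 26 others passed camera. The simulated genes varied independently, while the estimated correlation in the data was 0.25 for both the ciliated and the GTPase list. The simulation thus cannot show how often camera at the preset correlation calls lists whose genes vary together.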

Results

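Gene expression was measured in primary tracheal epithelial cells of male C57BL/6J mice, grown on porous membranes with their upper surface exposed to air, a culture form in which the cells form ciliated and secretory types. Wells received Sendai virus (SeV), a mouse paramyxovirus, or SeV inactivated by ultraviolet light (UV-SeV) on the upper surface for 1 h at 37 °C, and RNA was taken 24 h after inoculation. Each of 10 wells, 4 with SeV and 6 with UV-SeV, was hybridised to 1 Affymetrix mouse array with 12488 probe sets. Arrays are named here by group and by the number in their title. The comparison asks how airway epithelium responds to live virus over what the inactivated particles alone give. After a filter on dim probe sets, 4201 genes were tested, and the number of arrays limits the precision.

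The median over all probe sets was 3.64 (log2) on UV-SeV 3478, 3.65 on SeV 3479, 3.70 on UV-SeV 3480, 3.62 on UV-SeV 3482 and 3.87 on SeV 3483. It was 3.63 on SeV 3658, 3.59 on UV-SeV 3659, 3.63 on SeV 3660, 3.67 on UV-SeV 3661 and 4.04 on UV-SeV 3663. Array UV-SeV 3663 stood apart: its values correlated with those of the other arrays across probe sets at r = 0.843 to 0.901, while the other 9 arrays correlated with each other at 0.950 or more. The standard deviation of its values was 1.75, against 2.13 on SeV 3483 and 2.25 to 2.32 on the other 8 arrays. No 2 arrays held identical values, and the highest correlation between any pair was 0.995. The first principal component of the genes tested held 58.8% of the variance and set UV-SeV 3663 apart, and the next held 24.6% and separated SeV from UV-SeV.

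**Figure D1:**
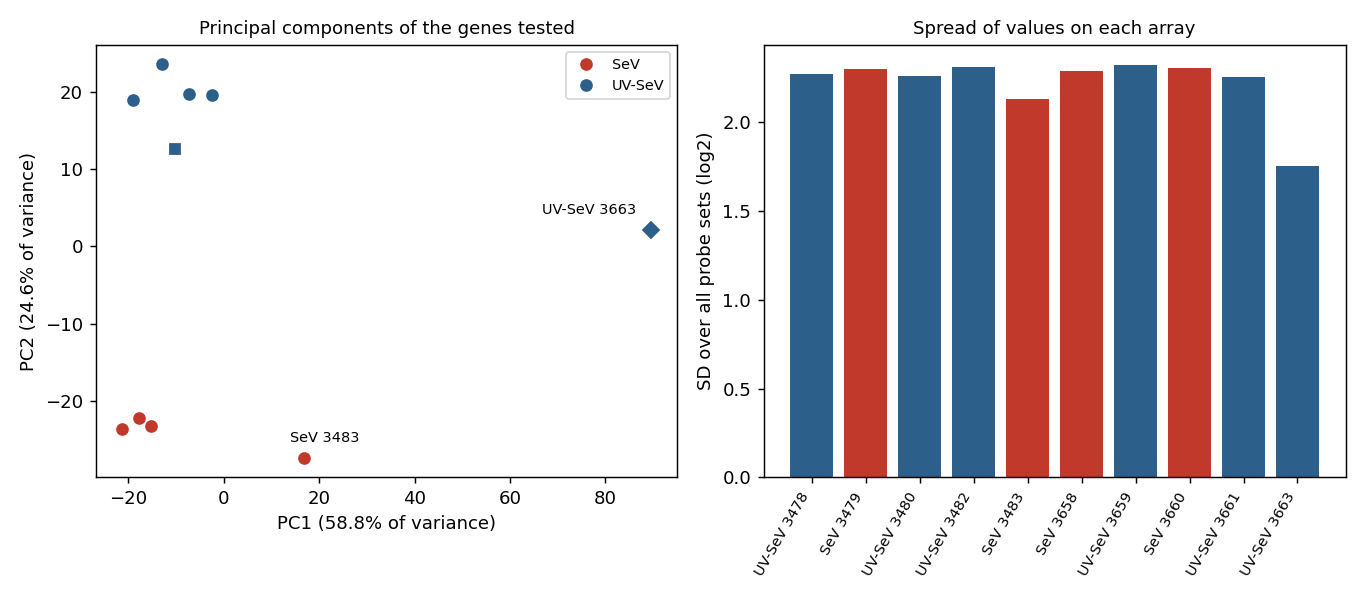
Left, the first 2 principal components of the genes tested on the 10 arrays (red, SeV; blue, UV-SeV; diamond, UV-SeV 3663; square, UV-SeV 3478), with the percent of variance on each axis. Right, the standard deviation of log2 values over all probe sets of each array, which was 1.75 on UV-SeV 3663 and 2.13 to 2.32 on the others.

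Genes of the interferon response and chemokines rose most in wells with live virus. Ccl5, a chemokine that attracts T cells and monocytes, rose from 4.26 ± 1.58 (log2, SD, n = 6) with UV-SeV to 11.38 ± 0.45 (SD, n = 4) with SeV, or at least 111-fold with values below 4 (log2) raised to 4. UV-SeV 3478 (7.40) lay above the other UV-SeV arrays (3.14 to 4.10) for Ccl5, and their mean of 3.63 was below the filter level. The log2 fold change as deposited was 7.12, and 7.75 without that array, which rests on these dim values. Gbp3 and Gbp2, guanylate-binding proteins that act against intracellular pathogens, rose 86.6-fold and 66.3-fold. Ifit2 and Ifit3, interferon-induced antiviral proteins, rose 66.8-fold and, with values below 4 raised to 4, at least 42.7-fold (log2 5.42, and 5.52 as deposited). Cmpk2, a mitochondrial nucleotide kinase induced by interferon, rose 46.5-fold, and AW112010, an interferon-induced transcript, 45.9-fold. Cxcl1, a neutrophil attractant, rose by a log2 of 5.54, or at least 34.7-fold with values below 4 raised to 4. These were the 8 largest increases by log2 fold change as deposited among genes whose SeV and UV-SeV arrays did not overlap. Their standard errors ran from 0.24 (Ifit3) to 0.74 (Ccl5) on the log2 scale, and their adjusted p from 1.72e-06 (Ifit3) to 0.000293 (Ccl5). The folds hold for the probe sets used. Dimmer probe sets that the filter left out gave log2 fold changes of 1.69 for Cxcl1 and 0.38 for Cmpk2.

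The 8 largest decreases were smaller. Slc16a7, a monocarboxylate transporter, fell by 2.25 ± 0.45 (log2 fold change ± SE), and Pdcd4, an inhibitor of translation, fell by 1.65 ± 0.37. Slc4a5, a sodium bicarbonate cotransporter, fell by 1.58 ± 0.18, and Cbr1, a carbonyl reductase, fell by 1.56 ± 0.25. Calml4, a calmodulin-like protein, fell by 1.54 ± 0.31, Tekt1, a filament protein of ciliary microtubules, fell by 1.46 ± 0.29, Dock9, an activator of the GTPase Cdc42, fell by 1.42 ± 0.27, and Acaa2, a thiolase of mitochondrial fatty acid oxidation, fell by 1.35 ± 0.23. Adjusted p lay between 0.000461 (Slc4a5) and 0.0366 (Pdcd4). Slc4a5, Cbr1 and Acaa2 passed with each array left out in turn. Pdcd4 lost its call without any 1 array other than UV-SeV 3663 (adjusted p up to 0.131), Slc16a7 without SeV 3479, SeV 3658, SeV 3660 or UV-SeV 3661 (up to 0.0724), Tekt1 without any of these or UV-SeV 3480 (up to 0.0804), Calml4 without SeV 3479 or SeV 3660 (up to 0.0700), and Dock9 without SeV 3658 (0.0609).

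In all, 169 of 4201 genes passed an adjusted p of 0.05, 130 higher and 39 lower with SeV. Of these, 115 were higher and 28 lower by at least 2-fold, and for 164 of the 169 the groups did not overlap. Over all 4201 genes tested, the groups did not overlap for 324, and chance gives that for 0.952% of genes. After quantile normalization the split was 143 higher and 94 lower. The total was 99 without SeV 3658, 104 without SeV 3660, 110 without SeV 3479, 112 without UV-SeV 3661 and 466 (218 higher, 248 lower) without UV-SeV 3663, which kept all 169 genes in the same direction. The count of lower genes was 11 without SeV 3658, 14 without SeV 3479, 16 without SeV 3660, 17 without UV-SeV 3480 or UV-SeV 3661, 18 without UV-SeV 3659, 24 without UV-SeV 3482 and 25 without UV-SeV 3478. The count of genes lower by at least 2-fold was 8 without SeV 3658, 9 without SeV 3479, 11 without UV-SeV 3661, 12 without UV-SeV 3480 or SeV 3660, 14 without UV-SeV 3659, 18 without UV-SeV 3478 and 117 without UV-SeV 3663. With each array left out in turn, 81 of the 130 higher and 9 of the 39 lower genes passed every time. The tests measure the spread between wells, which may share a cell preparation, so the p-values may cover technical spread in part.

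**Figure D2:**
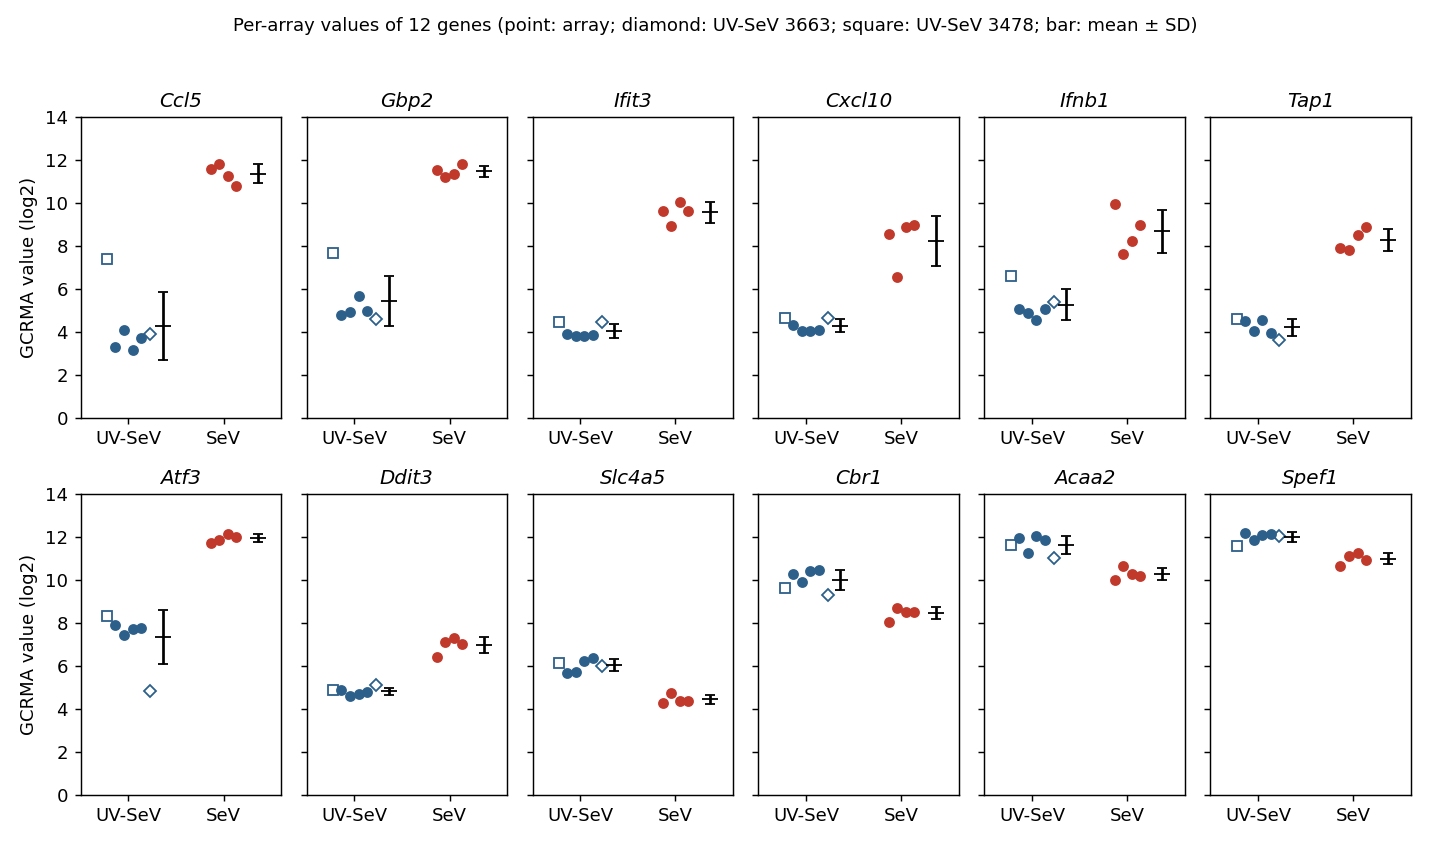
Log2 GCRMA values of 12 genes on each array (blue, UV-SeV, n = 6; red, SeV, n = 4; diamond, UV-SeV 3663; square, UV-SeV 3478), with the mean ± SD of each group as a black bar. For each of the 12 genes the SeV arrays lie all above or all below the UV-SeV arrays. UV-SeV 3478 is the highest UV-SeV array for Ccl5 (7.40), Gbp2 (7.66), Ifnb1 (6.61), Atf3 (8.33), Cxcl10 (4.65) and Tap1 (4.59), by a small margin for the last 2.

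Antiviral effectors of the interferon response rose together. Of 23 measured members of that list, 18 were higher, none lower and 5 not past the threshold, and 22 were higher adjusted over the list alone. Mx1, of a family of antiviral dynamin-like GTPases, rose 32.8-fold (log2 5.04 ± 0.32 SE, adjusted p = 1.12e-05), beside Ifit3 and Cmpk2. Of 10 interferon-inducible GTPases, 9 were higher and 1 was not past the threshold, and all 10 were higher adjusted over the list alone. Igtp, an immunity-related GTPase of intracellular membranes, rose 31.8-fold (log2 4.99 ± 0.31, adjusted p = 1.11e-05). Mx1 and Mx2 are in both lists, and Ifih1 is in the effector list and in that of viral RNA sensing. The camera test against all other genes gave an adjusted p of 6.90e-40 for the effectors and 7.33e-24 for the GTPases, and both calls held with an estimated correlation (0.00140 and 0.00246).

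Antigen presentation by MHC class I and chemokines also rose. Of 13 measured class I genes, 8 were higher and 5 not past the threshold, and 12 were higher adjusted over the list alone. Tap1, which carries peptides into the endoplasmic reticulum, rose 16.9-fold (log2 4.08 ± 0.28), and B2m, the light chain of class I molecules, 9.21-fold (3.20 ± 0.33). Psmb8, a subunit of the immunoproteasome, rose at least 15.2-fold with values below 4 raised to 4 (log2 3.92, and 4.09 ± 0.34 as deposited). Of 13 chemokines and cytokines, 8 were higher and 5 not past the threshold, also adjusted over the list alone. Cxcl2, a neutrophil attractant, rose at least 15.6-fold with values below 4 raised to 4 (log2 3.97, and 4.40 ± 0.20 as deposited, adjusted p = 1.72e-06), and Cxcl10, which attracts activated T cells, 15.4-fold (3.95 ± 0.44, adjusted p = 0.000461). Both lists passed camera (adjusted p = 7.12e-18 and 3.65e-13) and held with an estimated correlation (0.00140 and 0.00243). Of the MHC class II list only Ctss and Lgmn were measured, too few for a list test. Ctss rose 5.07-fold (adjusted p = 0.0394), a call lost without any 1 array other than SeV 3483 and UV-SeV 3663 (up to 0.147), and Lgmn lay at -0.35 ± 0.13 (adjusted p = 0.244), with 1 higher and 1 lower adjusted over the list alone.

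Ifnb1, which encodes interferon beta, rose 10.7-fold, from 5.27 ± 0.71 (SD, n = 6) to 8.69 ± 1.00 (SD, n = 4; log2 3.42 ± 0.49 SE, adjusted p = 0.00261). It was the 1 of 9 measured interferons and interferon receptors past the threshold, with 3 higher adjusted over the list alone. Ifnar2, a subunit of the type I interferon receptor, lay at 0.50 ± 0.15 (adjusted p = 0.116) and passed without UV-SeV 3663 (0.0465). The list passed camera (adjusted p = 0.00930), with adjusted p = 0.122 with an estimated correlation. Among 19 genes of viral RNA sensing and interferon signalling, 6 were higher and 13 not past the threshold, and 8 were higher adjusted over the list alone. Irf7 and Irf5, transcription factors of interferon genes, had UV-SeV means of 3.53 and 2.40, below the filter level of 4. With values below 4 raised to 4 they rose at least 6.16-fold (log2 2.62, and 3.09 ± 0.23 as deposited) and at least 1.49-fold (0.57, and 2.17 ± 0.13 as deposited). A probe set of Irf7 that the filter left out gave a log2 fold change of 2.17 as deposited. Of 10 feedback and adhesion targets of NF-kappaB, 3 were higher and 7 not past the threshold, and 6 were higher adjusted over the list alone. Icam1, which binds leukocyte integrins, rose 3.75-fold (log2 1.91 ± 0.21), and Relb, an NF-kappaB subunit, 2.22-fold (1.15 ± 0.21). Another kept probe set of Relb gave a log2 fold change of 0.16. The sensing list (camera adjusted p = 3.54e-08) and the NF-kappaB list (2.42e-07) held with an estimated correlation (0.00495 and 0.00626). On UV-SeV 3663 the mean of the NF-kappaB members was 5.40, against 5.82 to 5.97 on the other UV-SeV arrays.

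Stress response genes rose as a group. Of 20 genes of the integrated stress and unfolded protein responses, 7 were higher and 13 not past the threshold, the same counts as adjusted over the list alone. Atf3, a transcription factor of the stress response, rose 24.5-fold (log2 4.62 ± 0.58, adjusted p = 0.00110), and Ddit3, which encodes the stress factor CHOP, 4.46-fold (2.16 ± 0.18, adjusted p = 5.13e-05). Without UV-SeV 3663, the lowest UV-SeV array for Atf3, its log2 fold change was 4.12, and the median of the list was 0.40 against 0.66. The list passed camera (adjusted p = 7.65e-08) and held with an estimated correlation (0.0344). Of 12 cell death genes, 2 were higher and 10 not past the threshold, also adjusted over the list alone. Casp4, a caspase that senses bacterial lipopolysaccharide in the cytosol, rose 5.51-fold (log2 2.46 ± 0.18), and Bid, which promotes mitochondrial apoptosis, at least 1.90-fold with values below 4 raised to 4 (0.92, and 1.05 ± 0.24 as deposited, adjusted p = 0.0380). The cell death list passed camera at 0.00646, with adjusted p = 0.120 with an estimated correlation. On UV-SeV 3663 the mean of the stress members was 5.70, against 6.58 to 6.71 on the other UV-SeV arrays, and that of the cell death members 4.95, against 5.23 to 5.40. Bid lost its call without any 1 array other than SeV 3483 and UV-SeV 3663 (adjusted p up to 0.146).

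A few genes rose in lists of squamous, junction and macrophage genes. Of 9 squamous and injury keratins, 1 was higher and 8 not past the threshold, with 2 higher adjusted over the list alone. Sprr1a, a cornified envelope protein, rose 4.49-fold (log2 2.17 ± 0.46, adjusted p = 0.0289), and Krt6a, a keratin of wounded epithelium, lay at 1.96 ± 0.52 (0.0767). Of 11 genes of tight and adherens junctions, 1 was higher and 10 not past the threshold, with 2 higher adjusted over the list alone. Nectin2, a cell adhesion molecule, rose 3.31-fold (log2 1.73 ± 0.20, adjusted p = 0.000511), and F11r, a tight junction protein, lay at 1.08 ± 0.30 (0.0873). Of 8 macrophage and myeloid genes, 1 was higher and 7 not past the threshold, with 2 higher adjusted over the list alone. Ctss, a lysosomal protease of antigen-presenting cells, rose 5.07-fold (log2 2.34 ± 0.54, adjusted p = 0.0394), and Cd14, a receptor for lipopolysaccharide, lay at 1.55 ± 0.39 (0.0596). The other 6 members lay between 0.04 (Mrc1) and 0.33 (Laptm5). Camera gave 0.0399 for squamous genes, with adjusted p = 0.120 with an estimated correlation. That correlation was 0.00497 for the squamous list, under the preset 0.01, so it does not account for the higher p. Camera gave 0.00800 for junctions, with adjusted p = 0.179 with an estimated correlation, and 0.0345 for macrophage genes, with adjusted p = 0.306 with an estimated correlation. On UV-SeV 3663 the mean of the members was 6.57, 5.57 and 5.63 for these lists in that order, below the lowest other UV-SeV arrays at 7.52, 6.76 and 6.52.

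Leaving out 1 array changed calls among these genes and lists. The junction list lost its call without UV-SeV 3663 (adjusted p = 0.0577), the squamous list without UV-SeV 3480, UV-SeV 3482, SeV 3483 or UV-SeV 3659 (up to 0.229), and the macrophage list without SeV 3479, UV-SeV 3482 or SeV 3483 (up to 0.127). Sprr1a lost its call without any 1 array other than UV-SeV 3478, UV-SeV 3482 and UV-SeV 3663 (up to 0.103), and Ctss without any other than SeV 3483 and UV-SeV 3663 (up to 0.147) and with the run of title numbers as a block (0.0575). Krt6a (0.0166) and Cd14 (0.000284) passed without UV-SeV 3663, and F11r without SeV 3483 (0.00235). The log2 fold changes of Ctss and Sprr1a were smaller without UV-SeV 3663, at 1.91 and 1.79.

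Genes of cholesterol synthesis were higher as a list while none of its 13 measured members passed over all genes, and 1 was higher adjusted over the list alone. Cyp51 and Hsd17b7, enzymes of the late steps, lay at 0.75 ± 0.19 (adjusted p = 0.0669) and 0.58 ± 0.19 (0.175). The list passed camera (adjusted p = 0.00646) and held with an estimated correlation (0.0445). Without UV-SeV 3663, 3 members passed, among them Cyp51 (0.0253) and Hsd17b7 (0.0227), and Cyp51 also passed without SeV 3483.

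Ciliated cell genes were lower with SeV. Of 9 measured members, 2 were lower and 7 not past the threshold, with 3 lower adjusted over the list alone. Spef1, a microtubule-binding protein of cilia, fell by 1.00 ± 0.17 (log2, SE; adjusted p = 0.00765). Tekt1 fell by 1.46 ± 0.29 (0.0212), from 6.04 ± 0.59 (SD, n = 6) to 4.58 ± 0.22 (SD, n = 4), a call lost without SeV 3479, UV-SeV 3480, SeV 3658, SeV 3660 or UV-SeV 3661 (up to 0.0804). Foxj1, the regulator of motile ciliogenesis, lay at -0.38 ± 0.17 (adjusted p = 0.369). The list passed camera (adjusted p = 6.30e-06), with adjusted p = 0.0705 with an estimated correlation, and passed with each array left out in turn. Of 15 genes of fatty acid oxidation and synthesis, 1 was lower and 14 not past the threshold, with 2 lower adjusted over the list alone. Acaa2 fell by 1.35 ± 0.23 (adjusted p = 0.00790), and Cpt1a, which admits fatty acids to mitochondria, lay at -1.10 ± 0.31 (0.0892). That list passed camera (0.0491), with adjusted p = 0.418 with an estimated correlation. On UV-SeV 3663 the mean of its members was 6.40, against 7.34 to 7.65 on the other UV-SeV arrays, and on SeV 3483 it was 6.73, the lowest of the SeV arrays. The fatty acid list lost its call with the run of title numbers as a block (0.0539) and without SeV 3479, UV-SeV 3480, SeV 3483, UV-SeV 3659, SeV 3660 or UV-SeV 3661 (up to 0.112), and without UV-SeV 3663 it had 7 members lower, Cpt1a among them (0.00350), and 1 higher.

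**Figure D3:**
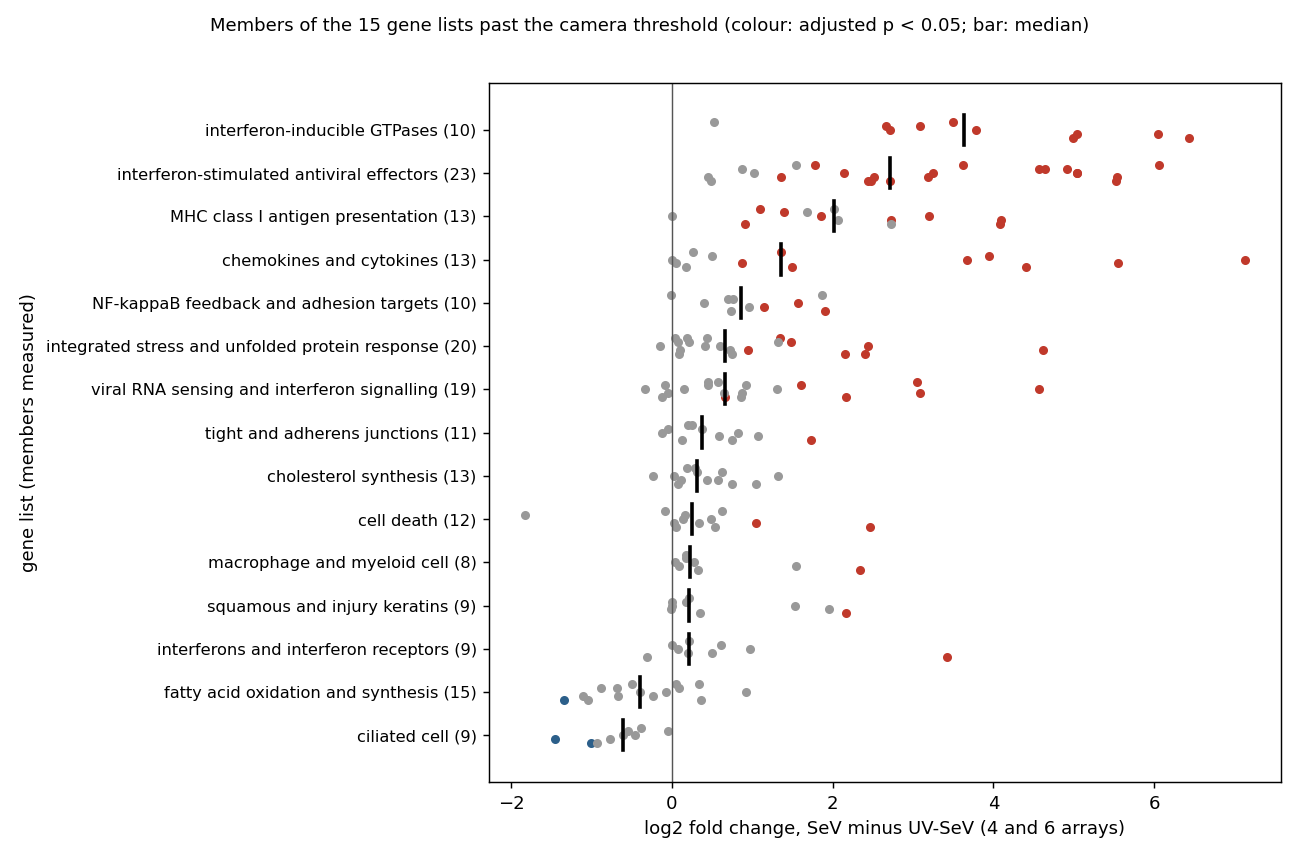
Log2 fold change (SeV minus UV-SeV; 4 and 6 arrays) of each measured member of the 15 gene lists past the camera threshold; red and blue points are genes higher and lower past an adjusted p of 0.05, grey points are not past it, and a black bar is the median of the list. The medians run from -0.60 for ciliated cell genes to 3.64 for interferon-inducible GTPases.

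The other 16 lists tested did not pass camera. Of 16 oxidative stress and NRF2 target genes (adjusted p = 0.0568), 2 were lower, also adjusted over the list alone: Cat, which breaks down hydrogen peroxide, fell by 1.30 ± 0.30 (0.0413), and Gstm1, a glutathione transferase, fell by 0.89 ± 0.19 (0.0230). Of 21 genes of the mitochondrial respiratory chain (0.0942) none passed. Without UV-SeV 3663 the NRF2 list (0.00771) and the respiratory chain list (0.0209) passed as lower, and the NRF2 list also passed without UV-SeV 3480 or SeV 3660. On all 10 arrays, both lists had adjusted p = 0.614 with an estimated correlation. Of 22 secretory and mucous cell genes (0.877), 2 were higher, also adjusted over the list alone: Slpi, a protease inhibitor of airway fluid, rose 3.15-fold (log2 1.66 ± 0.32), and Lcn2, which binds bacterial iron carriers, 2.10-fold (1.07 ± 0.20). Scgb1a1, the club cell secretoglobin, lay at -1.33 ± 0.74 (0.535). Cat lost its call without any 1 array other than UV-SeV 3663 (up to 0.130) and with the run of title numbers as a block (0.0575), Gstm1 without any other than SeV 3479, SeV 3483 and UV-SeV 3663 (up to 0.0954), and Slpi without SeV 3479 or SeV 3658 (up to 0.0652).

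Epithelial lists with no member past the threshold were basal cells (13 genes, camera adjusted p = 0.452), tuft cells, ionocytes and neuroendocrine cells (3 genes, 0.696) and ion and water transport (7 genes, 0.452). Lists of other cell types with none past it were lymphocytes (5 genes, 0.877), fibroblasts and smooth muscle (4 genes, 0.314) and endothelium and cartilage (4 genes, 0.950). The same held for heat shock proteins (11 genes, 0.974), glycolysis and hypoxia (15 genes, 0.920), cell cycle (9 genes, 0.859), p53 targets (10 genes, 0.862), ribosomal proteins (10 genes, 0.913) and complement (6 genes, 0.966). Adjusted over the list alone, 1 complement gene was higher and 1 lower, and 1 transport gene was lower. Complement had a mean of -0.21 and a camera direction of lower while fry gave higher, cell cycle a mean of 0.07 and a median of -0.04, and endothelium a median of -0.01 with a camera direction of higher. Of 9 reference genes (0.721), B2m rose, and Actb lay at -0.05 ± 0.23 (adjusted p = 0.996), at -0.14 after quantile normalization and at 0.23 in the first run of title numbers alone. Krt5 (1.93 with SeV, 1.97 with UV-SeV) and Muc5ac (3.83 and 3.82) were below the filter. No probe set of Gapdh alone was in the gene test, which left out control probe sets.

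The title numbers fall into 2 runs that each hold 2 SeV and 3 UV-SeV arrays, and the fold changes of the runs were compared across genes, which are not independent replicates. All 169 called genes changed in the same direction in both runs; the call itself used both. As deposited, Ccl5 rose by 6.78 in the first run and by 7.46 in the next, Ifnb1 by 3.26 and 3.58, and Spef1 lay at -0.99 and -1.01. Scgb1a1 lay at -0.02 in the first run and at -2.64 in the next (adjusted p = 0.0436 in that run alone), and the difference between runs did not pass (interaction adjusted p = 0.727). Over all 4201 genes the fold changes correlated at a Pearson r of 0.495 and a Spearman rho of 0.0948, and 47.3% had the same sign. Without UV-SeV 3663 these were 0.786, 0.557 and 67.2%. No gene passed the interaction of run and treatment in limma, and 57 had an unadjusted p under 0.05, a smaller share of genes than the 0.05 that chance gives. With 2 SeV and 3 UV-SeV arrays per run, the absence of calls does not show that the runs agree. With the run as a block, 179 genes passed, 138 higher and 41 lower, of which 160 were among the 169. The first run alone gave 81 genes (58 higher, 23 lower) and the other run 40 (39 higher, 1 lower), of which 63 and 39 were among the 169. The 1 lower gene of the other run was Scgb1a1, which is not among the 169. None of the genes called lower over both runs thus passed in that run alone.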

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

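The tests below were chosen only after the result was seen, except the exact permutation test of the ciliated list. In 168 groups of 4 or 6 arrays (named genes, means of the called lists and array measures), the gap of the most extreme array to its neighbour, as a share of the group's range, passed Dixon's critical value in 36, where chance gives about 1 in 20. Of these, 23 were on UV-SeV 3663, 7 on SeV 3483, 5 on UV-SeV 3478 and 1 on SeV 3479.

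On UV-SeV 3663 the gap was 0.751 of the range for the array median (4.04, highest), 0.881 for the SD over probe sets (1.75, lowest) and 0.632 for the actin 3' minus middle signal (5.04, highest). Genes lowest there among the UV-SeV arrays were Atf3 (gap 0.747), Ctss (0.777), Sprr1a (0.838), Slpi (0.641), Cd14 (0.751), Cat (0.673), Dock9 (0.71), Pdcd4 (0.634), Slc16a7 (0.753), Klf7 (0.804) and Cyp2b10 (0.649). Irf5 (0.799) and Saa3 (0.799) were highest there. Means of lists lowest there were those of NF-kappaB targets (0.723), cell death (0.631), the stress and unfolded protein responses (0.868), squamous genes (0.695), junctions (0.922), fatty acid genes (0.747) and macrophage genes (0.72).

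The slope of UV-SeV 3663 on the mean of the other UV-SeV arrays across genes was 0.614, against 0.886 to 1.02 for the other 9 arrays, with the brightest 25% of genes lower (median -1.70) and the dimmest 25% higher (0.41). This is consistent with a compressed signal range on that array. The tables argue against a response to live virus in that well as the whole cause: 2302 genes that SeV moved by under 0.25 (log2) without this array deviated there by a median absolute amount of 0.60 (interquartile range 0.31 to 1.20), against medians of 0.10 to 0.31 on the other 9 arrays. The mean of the heat shock list, not called in SeV, was 6.51 there against 8.38 to 8.98 on the other UV-SeV arrays. A response as large as in SeV wells is also argued against. With the trend by signal level removed, the 31 members of the antiviral effector and GTPase lists deviated by a median of -0.13 (interquartile range -0.93 to 0.28), where their median SeV change of 3.01 times the slope gives 1.85. The mean of the effectors was lowest there among the UV-SeV arrays (4.99, against 5.36 to 5.94). A weaker response beside another cause stays open: the 218 genes higher in SeV without this array deviated, with the trend removed, by a median of -0.10, but both ways (interquartile range -0.75 to 0.43). On the principal component that separated SeV (-27.36 to -22.18) from the other UV-SeV arrays (12.57 to 23.53) it lay between them, at 2.12. Degraded RNA stays open: the actin 3' minus middle signal of 5.04 lay above the other arrays (3.67 to 4.45), while that of Gapdh (4.77) lay within theirs (3.99 to 4.78), as did the actin 3' minus 5' signal (8.53, against 7.62 to 9.12). No other biological explanation particular to this well was tested.

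UV-SeV 3478 was the highest UV-SeV array for Ccl5 (7.40, gap 0.775), Gbp3 (6.63, 0.64), Gbp2 (7.66, 0.644), Cmpk2 (6.68, 0.761) and Mx1 (7.20, 0.822), and for 13 of 31 members of the antiviral effector and GTPase lists. UV-SeV 3663 was highest for 9 of these and each of the other 4 UV-SeV arrays for 1 to 4. For Ifnb1, UV-SeV 3478 was also highest (6.61, against 4.57 to 5.39 on the other UV-SeV arrays), with a gap short of Dixon's critical value. The tests of this array set it against the other 4 UV-SeV arrays with UV-SeV 3663 left out. A general shift of its signal is argued against: genes not past the threshold deviated by a median of -0.0242 (interquartile range -0.19 to 0.10), and the 31 members by 0.31. This test was first run over all 130 higher genes, whose median deviation of 0.11 decided nothing, and was then narrowed to the list members. RNA of a SeV well mixed in could account for the pattern: over 17 genes at least 8-fold higher in SeV and above 5 in UV-SeV, a single share of 3.96% left a residual of 0.950 times the spread expected from those 4 arrays, and 14 of the 17 lay above their mean. The expected spread is wide, and the share implied by single genes ran from -4.70% (Vnn1) to 10.4% (Crct1), so this test has little power to reject a single share. A weak response of the cells in that well, to remaining live virus or otherwise, stays open and untested.

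Ciliated cell genes were lower with SeV, with a mean over 9 members of 6.56 ± 0.19 (SD, n = 4) against 7.25 ± 0.30 (SD, n = 6). For this list, spread between wells alone is argued against by an exact two-sided permutation test of that mean over 210 splits (p = 0.00952). Among the 31 lists tested with camera, only this 1 was also tested by permutation, and its p was not adjusted over the lists. Without UV-SeV 3663 the permutation test gave p = 0.0159 over 126 splits. That array alone is also argued against, since without it the list passed that test, and camera at the preset correlation (adjusted p = 0.00130). With an estimated correlation, on all 10 arrays, the list did not pass camera (adjusted p = 0.0705). A lower share of ciliated cells in SeV wells may be part of it and cannot be told apart from lower expression per cell: only 3 members lay above 6 (log2), and the highest (Tuba1a, -0.77) and the lowest of them (Spef1) differed by 0.529 standard errors. An effect of infection on expression within ciliated cells was not tested.

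On SeV 3483 the gap was 0.915 for the array median (3.87, highest) and 0.901 for the SD over probe sets (2.13, lowest). Gbp3 (9.93, gap 0.876), Acod1 (4.54, 0.883) and the mean of fatty acid genes (0.917) were lowest there among the SeV arrays, and Irf7 (7.35, 0.923) and Il18bp (6.17, 0.848) highest. On SeV 3479, Foxj1 was lowest among the SeV arrays (5.13, gap 0.869).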

How the results depend on the processing

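Leaving out UV-SeV 3663 and SeV 3483 together and the alternatives for the agreement of the runs were tested only after the result was seen, and the others were planned. No paired analysis was possible because SeV and UV-SeV arrays share no replicate number. Of 64 genes whose values were followed, 54 passed the threshold and 38 of these passed with each array left out in turn. Over all alternatives, 1205 of 1395 values of named genes and 547 of 644 of the lists kept direction and side of the threshold, 155 and 35 lost the threshold, 30 and 13 gained it, and 4 and 49 changed direction without passing it before or after. Acod1 reversed, at -0.0548 after quantile normalization, because another of its probe sets then stood for it. Dim genes limit what can be seen, and how far values near background follow a change was not tested.

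The 39 lower genes (28 by at least 2-fold) became 94 (52) after quantile normalization and 71 (53) with a common median. Array weights gave 775 genes, 363 higher (180 by at least 2-fold) and 412 lower (116). Leaving out UV-SeV 3663 and SeV 3483 gave 541, 290 higher and 251 lower (92 by at least 2-fold), with 166 of the 169 among them. Run 1 alone gave 81, 58 higher (58 by at least 2-fold) and 23 lower, and run 2 alone 40, 39 higher (39) and 1 lower (1), with fewer arrays. An adjusted p of 0.01 gave 84, 76 higher (72) and 8 lower (6), and treat 66, 65 higher and 1 lower, both stricter by construction. For the other settings the cause was not tested.

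With 1 array left out, the total ran from 99 (without SeV 3658) to 466 (without UV-SeV 3663), genes higher from 88 to 218, genes lower from 11 to 248 and genes lower by at least 2-fold from 8 to 117, and lists lower from 1 to 4. The 2 lower lists were 1 with no filter, with trend and robust options, with the run as a block and with fry. They were 4 with quantile normalization, a common median, array weights, and both arrays left out. Camera with an estimated correlation kept 8 lists, 8 higher and 0 lower. The run as a block ended the calls of the fatty acid list, Ctss and Cat and no other among these lists and genes. The correlation of the runs across genes (Pearson 0.495, Spearman 0.0948) was 0.786 and 0.557 without UV-SeV 3663, 0.903 and 0.737 without UV-SeV 3663 and SeV 3483, and 0.388 and -0.109 with no filter, where Spearman's reversed. The interaction gave 0 genes in each, with 129, 115 and 111 at an unadjusted p under 0.05, and 72 with quantile normalization. Each count is a smaller share of genes than the 0.05 that chance gives.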

Other observations

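The genes of the next paragraph, Aox1, Cyp2b10, Aldh2, Klf4, Klf6 and Klf7, the tests of enzyme families without the genes that fell and by permutation, and the weighing of the Klf test by its spread, were chosen only after the result was seen; the other tests were set before theirs was seen.

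Several genes outside the lists rose with live virus. Acod1, which makes the metabolite itaconate, rose at least 6.69-fold with values below 4 (log2) raised to 4 (log2 2.74, and 3.89 ± 0.54 SE as deposited, adjusted p = 0.00223). Its log2 fold change as deposited was 4.63 without SeV 3483, and -0.0548 after quantile normalization on another probe set. Vnn1 and Vnn3, pantetheinases, rose 12.1-fold and 5.33-fold, and Defb1, an antimicrobial defensin, 7.19-fold. Il18bp, a secreted inhibitor of interleukin 18, had a UV-SeV mean of 2.30 and rose at least 2.48-fold with values below 4 raised to 4 (log2 1.31, and 3.01 as deposited). Osmr, a receptor for oncostatin M, rose 5.42-fold (2.44 ± 0.16), and Ptgs2, the inducible cyclooxygenase, 3.62-fold. Saa3, an acute phase protein, rose at least 3.95-fold with values below 4 raised to 4 (log2 1.98, and 2.07 as deposited). SeV arrays lay above all UV-SeV arrays for each of these genes, and those other than Ptgs2 passed with each array left out in turn. Ptgs2 lost its call without SeV 3479, SeV 3658 or SeV 3660 (adjusted p up to 0.0705).

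Enzymes that act on aldehydes, carbonyls and foreign compounds were among the genes that fell. Beside Cbr1 and Gstm1, Aox1 fell by 1.23 ± 0.17 (log2, SE; adjusted p = 0.00170), Cyp2b10 fell by 1.14 ± 0.25 (0.0327), and Aldh2 fell by 0.66 ± 0.11 (0.00689). The hypothesis was that these families (symbols that start with Aldh, Akr, Cbr, Cyp, Gst, Aox, Fmo, Ephx, Ugt or Sult) lie lower as a whole. Of 40 measured members, 5 were lower, 0 higher and 31 below 0, with a median of -0.32, and camera gave p = 1.07e-06 with the preset correlation. An exact two-sided permutation test of the mean of the 40 over 210 splits gave p = 0.0476. Without the 5 that gave the idea, the other 35 had a median of -0.20, a camera p of 0.00109 and an exact permutation p of 0.224. With an estimated correlation the p was 0.0820 for the 40 and 0.201 for the 35. Whether the families moved beyond these 5 stays open, since the shift of the others may rest on genes that vary together between wells. Without UV-SeV 3663, 16 members were lower and 1 higher. Cyp2b10 lost its call without any 1 array other than UV-SeV 3663 (adjusted p up to 0.127), and Gstm1 without any other than SeV 3479, SeV 3483 and UV-SeV 3663 (up to 0.0954).

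Klf6, Klf4 and Klf7, Kruppel-like transcription factors, rose 5.56-fold, 4.68-fold and 2.02-fold (adjusted p = 0.0212, 0.0297 and 0.0216). The hypothesis that the family lies higher as a whole failed the rule set beforehand, since the median of the other 6 members lay under its bound. That median was 0.19 (interquartile range 0.02 to 0.50, from -0.31 to 0.94), and 0 of them passed. Weighed by this spread, a step chosen later, the hypothesis stays open. Klf4 lost its call without any 1 array other than UV-SeV 3482, SeV 3483 and UV-SeV 3663 (up to 0.117), Klf6 without SeV 3479, SeV 3658, SeV 3660 or UV-SeV 3661 (up to 0.0800), and Klf7 without SeV 3479, SeV 3483, SeV 3658 or SeV 3660 (up to 0.0901).

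Of 100 splits of the 10 arrays into 4 and 6, the real one included, 1 gave as many as 169 genes, and the highest other gave 2. For genes changed at least 2-fold, 1 gave as many as 143, and the highest other gave 2. Chance is unlikely for both counts, and 1 in 100 is the lowest share that this number of splits can give. For lists past camera, 3 of 100 splits gave 15 or more: the real one, 1 with 16 (arrays 3478, 3479, 3658 and 3663 together) and 1 with 15 (arrays 3478, 3480, 3659 and 3661 together), with a median of 3 over the others. The split with 15 held no SeV array, so all 4 SeV arrays lay together in its other group, and the split with 16 held 2. Such splits carry part of the difference between treatments and are not free of it. The share lay under the bound set beforehand. Still, 1 other split called more lists than the real one, so this test does not exclude chance for the number of lists. The count of lists alone says less than the genes do.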
